A study of Mus musculus with 40 samples.

How the data were processed

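RNA was measured in perfused brain of 40 mice, collected 5 days after CLP, which the labels describe as sepsis, or after anesthesia. For the anesthesia mice no time of collection was recorded here. The mice carried the 5xFAD transgenes, which hold human coding sequence in a Thy1 expression cassette, or were wild type (Wt). Libraries were QuantSeq 3' mRNA libraries with molecular identifiers, so reads came from transcript ends, per the labels' protocols. The same protocol text names lung as the tissue, while every sample label names brain. Group, sex and genotype were taken from the labels, and the replicate numbers used here follow the order of the samples and pair no mice.

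The deposited values are variance-stabilised expression values on a log2-like scale, 1 column per mouse, with 23421 gene symbols. Per the submitters' processing notes, the tools were FastQC, Trim Galore 0.5.0, STAR 2.6.0, featureCounts and DESeq2 1.22.2 with build GRCm38. Their settings, the strand setting of the counting, the annotation release and the filter on genes are not given in the sources used here. All 40 columns shared a floor of 5.27 on the log2 scale, the value of 0 reads. Undoing the transformation gave whole reads within 0.01 reads for 100% of values in every library, and rebuilding the deposited log2 values from them left a largest difference of 6.9e-14. The smallest sum of a gene over the libraries was 10 reads. Levels below are these reads divided by the library's size factor, called normalised reads. The main test was run on the deposited log2 values.

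Differences were tested on the deposited log2 values with limma 3.58.1 in R 4.3.3, with group and labelled sex in the model, all 40 mice in 1 fit, an intensity trend in the spread, and Benjamini-Hochberg adjustment within each contrast at 0.05. The contrasts were CLP against anesthesia in each genotype, 5xFAD against Wt after each treatment, the difference between the CLP responses, and female against male. In the 25 CLP mice alone, the genotype difference was also compared between the sexes. Log2 differences understate the change of genes with few reads, since the transformation flattens low values. The agreement of contrasts was set against 100 labellings, the real one included. Each of 41 gene lists (cell types, brain regions, pathways) was tested with fry from limma, which asks whether a list moves on balance one way and does not compare it with other genes, and with camera using an estimated correlation or a preset one of 0.01. Some lists share members, so their results are not independent. Lcn2 is in the vascular and the reactive astrocyte lists, and C4b in the reactive astrocyte and the complement lists.

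The contrasts, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took, among genes past the threshold and above the 25th percentile of mean value, the 12 with the largest difference each way (6 for the sex contrasts), and up to 4 members of each list. Where no gene passed, it took the 5 with the smallest p. App, Thy1, Gfap, Trem2, Cst7, Lcn2, S100a8, S100a9, Il1b, C4b and Fkbp5 were included in all 5 treatment and genotype contrasts whatever their values, and the sex-linked genes in the sex contrast. Tnf was on the same list and was not analysed here, and 1 further gene of that list is not reported here. Alternatives covered the sex term, the mice in the fit, each mouse left out, the estimate of the spread, scaling, a filter on low values and covariates. Chosen after the data were seen were voom from limma on the recovered reads (once with a changed sex label), total reads as a covariate, a changed sex label for 1 mouse, and fits by library number.

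Library numbers in the labels run from 39 to 46 and from 62 to 78 in CLP mice and from 47 to 61 in anesthesia mice. They served as a possible batch, whose nature the labels do not give. Only CLP mice had numbers of 62 and above. A term for these numbers therefore left the CLP effect mainly to CLP libraries 39 to 46. Such fits are not independent of the fits to that range. Total reads were 2461283 to 4793275 per library with a median of 3015068, and 18847 to 20884 genes had reads. Pairs of libraries correlated at 0.975 to 0.993, and the pair closest to counting noise had a chi-square per degree of freedom of 1.63 (median 4.03 over pairs), so no library was treated as a duplicate. Simulated data had up to 200 changed genes counted for recovery, drawn from genes above a low minimum of mean reads. The cholesterol synthesis list was raised as well, and its genes were counted neither as recovered nor as false calls. The simulated libraries had the same spread setting for every gene, and no differences by library number or sex. On them the procedure recovered 74.6% of genes changed 1.5-fold and 94% of those changed 2-fold for CLP in Wt. For the difference between the CLP responses it recovered 58.2% and 78.8%. Recovery in the real data may be lower. False calls numbered 20 for CLP in Wt, 8 for CLP in 5xFAD, 14 and 5 for genotype after anesthesia and after CLP, and 8 for the response difference. For CLP in Wt and genotype after anesthesia this was more than the threshold of 0.05 allows on average. Gene positions came from a GRCm38 annotation, which held 22870 of the 23421 symbols (97.7%). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.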

Results

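Brain transcript levels were compared among 6 Wt mice after anesthesia, 14 Wt mice after CLP, 9 5xFAD mice after anesthesia and 11 5xFAD mice after CLP. The labels give 5 females and 1 male, 7 and 7, 1 and 8, and 6 and 5 in these groups. Median depth was 2895184, 3074028, 2977691 and 2973749 reads, and the labels do not say more about the mice than genotype, treatment and sex.

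Labels were compared with transcripts first. Neuronal Snap25 (median 4190 normalised reads, lowest 3169), myelin Mbp (6245) and astrocytic Slc1a2 (6704) were abundant in all 40 libraries, whereas the lung surfactant gene Sftpc had a median of 1.85 and a highest value of 21.7. The airway genes Scgb3a1, Scgb1a1 and Sftpa1 reached up to 64.8, 39 and 15.5 normalised reads, with medians of 8.59, 3.23 and 0. Thy1, whose regulatory sequences drive the transgenes, stood at 6538 ± 854 (SD, n = 9) and 8245 ± 1514 (SD, n = 11) in 5xFAD mice, against 2433 ± 515 (SD, n = 6) and 2276 ± 462 (SD, n = 14) in Wt mice. Whether these 3' reads include transgene cassette sequence was not analysed here, and Thy1 served as a genotype marker only. Xist, the RNA of the inactive X chromosome, had 674 to 1091 normalised reads in 18 libraries labelled female and 0 to 14.5 in the 21 labelled male. The library labelled female 5xFADAnesthesia replicate 1 had 14.1 Xist reads and 35.2 of the Y-linked Eif2s3y, for which male-labelled libraries spanned 20.9 to 68.4. It was kept with its label in the fits, and changes of that label are given where they mattered.

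**Figure D1:**
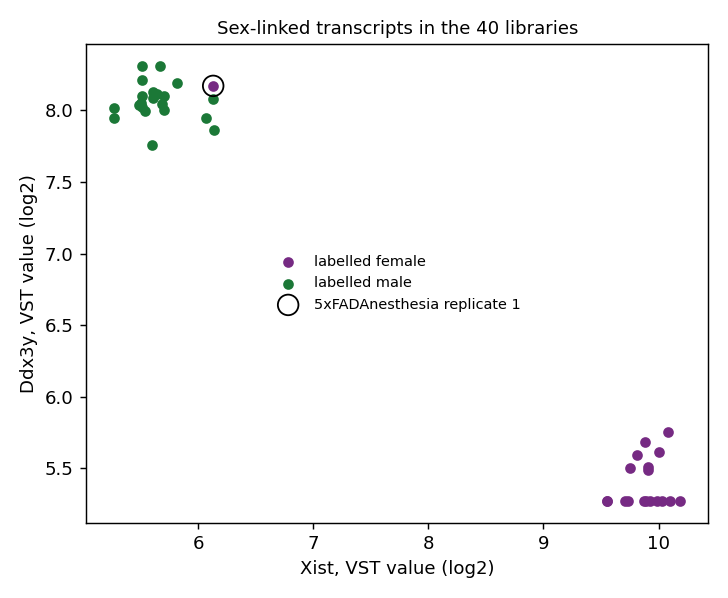
Xist (horizontal) and Ddx3y (vertical) in each of the 40 libraries, as variance-stabilised log2 values, coloured by the sex label. The circled library labelled female, 5xFADAnesthesia replicate 1, lies with the 21 libraries labelled male.

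The response to CLP in Wt mice was led by inflammatory and vascular genes. Lrg1, an acute-phase glycoprotein (chromosome 17, 56119678 to 56122001, GRCm38), rose 8.03-fold, from 7.90 ± 3.74 normalised reads (SD, n = 6) to 63.4 ± 17.9 (SD, n = 14), a log2 difference of 1.07 ± 0.11 (SE, limma adjusted p = 1.91e-09, higher in 14 of 14 mice). Lcn2, a siderophore-binding protein, rose from 0.346 ± 0.536 to 16.3 ± 7.69 normalised reads (log2 difference 0.82 ± 0.12, adjusted p = 5.35e-05). The endothelial surface genes Ly6c1 and Ly6a rose 1.98-fold and 2.06-fold (log2 differences 0.76 ± 0.10 and 0.76 ± 0.11), and Ch25h, an oxysterol-producing hydroxylase, rose 9.86-fold (0.60 ± 0.09). Scgb3a1, a secretoglobin of airway epithelium, rose 12.7-fold (0.69 ± 0.10, adjusted p = 4.43e-05). S100a8 and S100a9, the subunits of calprotectin, rose 21.7-fold and 26.2-fold (1.38 ± 0.29 and 0.95 ± 0.21) with wide spread between mice, S100a8 spanning 14.2 to 834 normalised reads over the 14 mice. Each of these genes was above the anesthesia mean in 14 of 14 mice, and each had a positive difference in libraries 39 to 46 and 62 to 78 (Lrg1 1.24 and 0.98, Lcn2 0.93 and 0.74, S100a8 0.89 and 1.58). Without WtAnesthesia replicate 3 the adjusted p of S100a8 was 0.0882 and that of S100a9 was 0.115, and without WtAnesthesia replicate 2 that of S100a9 was 0.0507. Both calls held with only CLP libraries 39 to 46 and with only 62 to 78, but were also lost in other fits. The adjusted p of S100a8 and S100a9 was 0.147 and 0.0706 by voom, 0.417 and 0.451 with a term for library numbers of 62 and above, and 0.0711 and 0.09 with a robust spread. It was 0.0597 and 0.106 in females only, and 0.11 and 0.137 without the 2 mice of the rarer labelled sex under anesthesia. Of these 2, 5xFADAnesthesia replicate 1 was labelled female but had Xist at the male level, like the rest of its group.

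Among fixed lists, the vascular response to systemic inflammation rose in Wt mice (fry adjusted p = 1.96e-06, median log2 difference 0.14, score higher in 14 of 14 mice), with 8 of 24 members higher, 0 lower and 16 not past the threshold, and 11 higher when adjusted over the list alone. Cebpd and Ctla2a were among them, at 1.83-fold and 4.33-fold. The endothelium list rose (adjusted p = 0.000938, median 0.06, 14 of 14 mice, 3 of 18 members higher, 5 higher and 1 lower adjusted over the list alone). Reactive astrocyte genes rose (adjusted p = 6.63e-06, median 0.10, 14 of 14 mice), with 3 of 15 higher, 6 adjusted over the list alone, including Cp (1.68-fold) and Osmr (2.94-fold), while Gfap itself was at 123 ± 25.4 against 116 ± 22.4 normalised reads (adjusted p = 0.864). Complement and Fc receptor genes (adjusted p = 0.000938, median 0.15, 14 of 14 mice, 1 of 18 higher, 9 adjusted over the list alone) and monocyte and border macrophage genes (adjusted p = 0.00127, median 0.14, 14 of 14 mice, 0 of 15 past the threshold singly, 3 adjusted over the list alone) rose. Neutrophil genes rose (adjusted p = 0.00816, median 0.16, 14 of 14 mice), with 3 of 15 higher and 6 adjusted over the list alone. The neutrophil list was called in 9 of 10 alternative settings. With a term for library numbers of 62 and above it had adjusted p = 0.18, and the score of WtCLP replicate 11 was 0.86 with 0.276 as the next highest. Cytosolic ribosome genes rose (adjusted p = 0.00338, median 0.17, 13 of 14 mice, 2 of 53 higher, 33 adjusted over the list alone), which are uncertain since ribosomal genes have many processed pseudogenes. Their score was -0.299 to -0.088 in WtAnesthesia replicates 2 to 5, but 0.045 and 0.033 in replicates 1 and 6. In WtCLP replicate 13 it was -0.208. The interferon list (adjusted p = 0.0142, 13 of 14 mice) and the ketone and fasting list (0.00816, 12 of 14 mice) also rose, with medians of 0.12 and 0.05, but each had adjusted p = 0.0757 by camera with an estimated correlation. The interferon list had adjusted p = 0.0532 with median centring. The ketone and fasting list had 0.147 in libraries 39 to 46 and 0.0796 with the number term. Cp had adjusted p = 0.0948 with that term, and Osmr had 0.0997 in females only.

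Excitatory and synaptic transcripts were lower after CLP in Wt mice. Nrgn, a postsynaptic calmodulin-binding protein (chromosome 9, 37544492 to 37552904, GRCm38), was 1.27-fold lower (11650 ± 1694 normalised reads, SD, n = 14, against 14810 ± 573, SD, n = 6, limma adjusted p = 0.0280). The neuropeptide precursor Vgf was lower, at 903 against 1176 normalised reads (log2 difference -0.36 ± 0.07, adjusted p = 0.00387). The transcription factor Nfix (-0.49 ± 0.08), the formin Fmnl1 (-0.45 ± 0.08) and Hrk, a pro-apoptotic BCL-family gene (-0.37 ± 0.07), were lower in 14 of 14 mice. The activity-induced transcription factors Egr1 and Egr3 were lower at -0.45 ± 0.10 and -0.34 ± 0.07, in 13 and 14 of 14 mice. In females only the adjusted p was 0.0606 for Nfix, 0.0714 for Fmnl1, 0.0786 for Nrgn and 0.122 for Egr1. The excitatory and pan-neuronal list fell (fry adjusted p = 0.000937, median -0.12, 14 of 14 mice, 2 of 18 members lower, 6 lower and 1 higher adjusted over the list alone). The synaptic list fell (adjusted p = 0.00127, median -0.08, 13 of 14 mice, 2 of 24 lower, 7 lower and 1 higher adjusted over the list alone). It shares Snap25, Syp, Syt1, Grin1 and Grin2b with the excitatory list, so these results are not independent. The lists of inhibitory neurons (adjusted p = 0.194, median -0.03), striatum (0.29, median -0.06), hippocampus (0.791, median -0.01) and cerebellum (0.896, median -0.02) did not pass. Oligodendrocyte precursor genes fell (adjusted p = 0.00146, median -0.07, 14 of 14 mice, 0 of 12 past the threshold singly, 5 lower adjusted over the list alone). Immediate early genes fell (adjusted p = 0.0450, median -0.22, 12 of 14 mice, 4 of 19 lower, 10 adjusted over the list alone), with adjusted p = 0.0757 by camera with an estimated correlation and 0.0567 with the mouse of doubtful sex as male. In libraries 39 to 46 the adjusted p was 0.125 for the neuronal list, 0.353 for the precursor list, 0.849 for immediate early genes and 0.0105 for the synaptic list, which had adjusted p = 0.143 with quantile normalization, and Nrgn had a log2 difference of -0.14 (adjusted p = 0.849) against -0.47 in libraries 62 to 78. A term for library numbers of 62 and above, which only CLP mice had, also left the CLP effect mainly to libraries 39 to 46. With it the adjusted p was 0.0664 for the excitatory list, 0.12 for the oligodendrocyte precursor list and 0.64 for the immediate early genes. With that term it was 0.741 for Nrgn, 0.153 for Vgf, 0.26 for Nfix, 0.272 for Hrk, 0.527 for Egr1 and 0.209 for Egr3. The call of Nrgn was lost without any 1 of WtAnesthesia replicates 1 to 5 or WtCLP replicates 7, 8, 11 and 12 (adjusted p in this order 0.0591, 0.0502, 0.109, 0.055, 0.0552, 0.0575, 0.0537, 0.0699 and 0.0512). That of Egr1 was lost without WtAnesthesia replicates 3, 4 or 5 or WtCLP replicate 11 (0.06, 0.0533, 0.0656 and 0.051), and that of Egr3 without WtAnesthesia replicates 1 or 4 (0.0591 and 0.055).

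In all, 141 genes passed the threshold after CLP in Wt mice, 67 higher and 74 lower, of 23421 tested. Quantile normalization gave 78 (51 higher, 27 lower) and median centring 158 (47 higher, 111 lower), so the balance of higher and lower genes depended on the scaling. In females only it was 65 (48 higher, 17 lower). With only CLP libraries 39 to 46 the count was 22, and with only 62 to 78 it was 732. Of the 67 higher genes, 18 were called in libraries 39 to 46 and 62 in libraries 62 to 78. Of the 74 lower genes, 2 and 72 were called. The median log2 difference of the lower genes was -0.18 in libraries 39 to 46 and -0.33 in 62 to 78, and that of the higher genes 0.30 and 0.34. Between CLP libraries 62 to 78 and 39 to 46 themselves, with genotype and sex in the model, 1278 genes differed (640 higher, 638 lower), more than in any contrast of treatment or genotype. Without WtCLP replicate 1 the count was 253. It was 88, 91, 49, 61 and 74 without WtAnesthesia replicate 1, 2, 3, 4 and 5 in turn, and 84, 61 and 79 without WtCLP replicate 7, 11 and 12. Red blood cell genes had a median log2 difference of -0.19 (fry adjusted p = 0.161), choroid plexus genes -0.01 (0.512) and lung genes 0.01 (0.278). In libraries 39 to 46 the lung list was higher (adjusted p = 0.00998, median 0.09), and in 62 to 78 it had 0.191. Il1b (0.12 ± 0.07, adjusted p = 0.531), Fkbp5 (0.19 ± 0.11, 0.529), C4b (0.10 ± 0.09, 0.735) and App (-0.06 ± 0.05, 0.681) did not pass the threshold. Nor did Thy1 (-0.11 ± 0.11, 0.751), Trem2 (0.016 ± 0.09, 0.971) or Cst7 (-0.016 ± 0.14, 0.980).

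**Figure D2:**
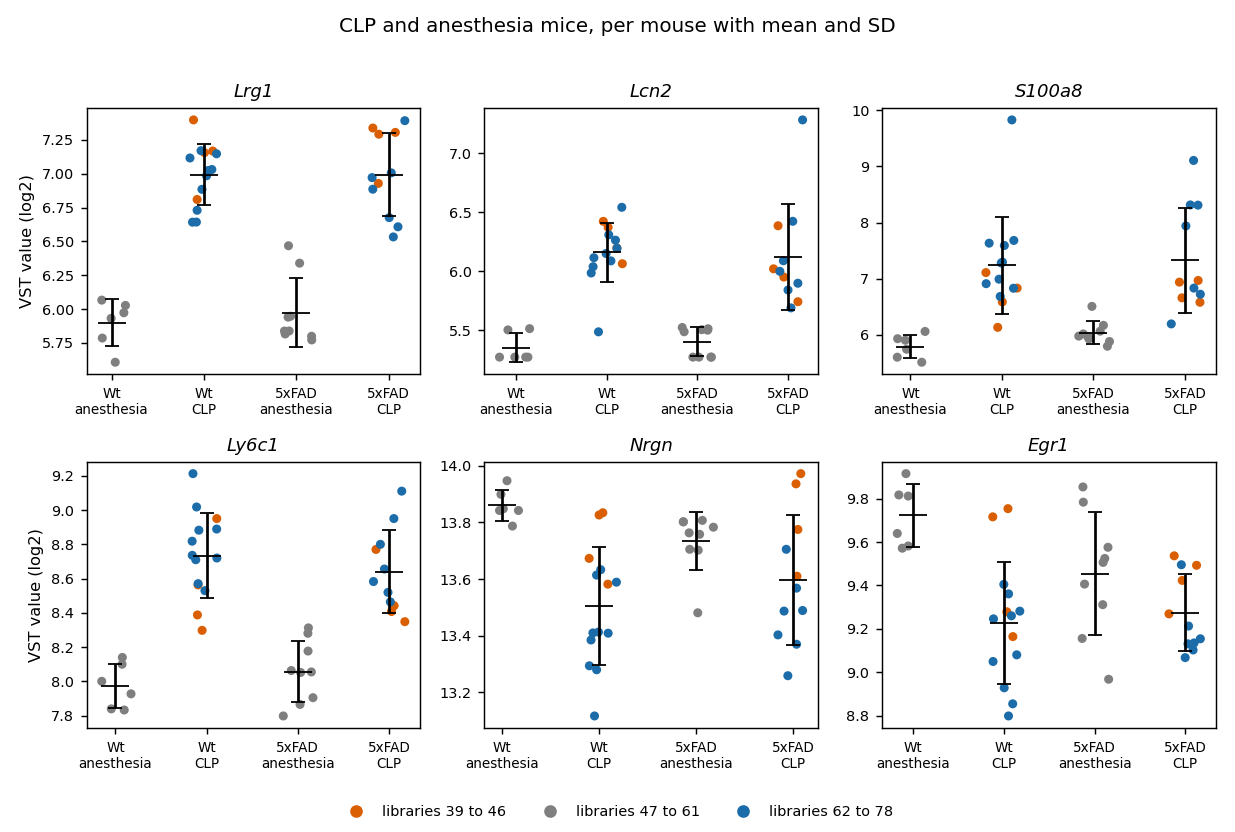
Variance-stabilised log2 values of 6 genes per mouse in the 4 groups, with group mean and SD in black and points coloured by library number. Lrg1 and Ly6c1 were higher after CLP in both genotypes. The genes called higher in 5xFAD mice in both library ranges included Lrg1 but not Ly6c1. Nrgn and Egr1 were lower after CLP in Wt mice, mainly in libraries 62 to 78.

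In 5xFAD mice, CLP was followed by a rise in many of the same genes. Lrg1 rose 6.15-fold (64.8 ± 24.7 normalised reads, SD, n = 11, log2 difference 1.05 ± 0.10, adjusted p = 5.40e-10), and Lcn2 rose from 0.565 ± 0.542 to 18.3 ± 24.3 normalised reads (0.70 ± 0.12, adjusted p = 0.000484). Scgb3a1 rose from 0.224 ± 0.444 to 20.1 ± 16.4 (0.87 ± 0.10, adjusted p = 4.51e-08). Igfbp7, a secreted vascular protein, rose 2.05-fold (0.49 ± 0.07), Podxl, an endothelial sialomucin, 1.53-fold (0.45 ± 0.08) and the complement gene C1qb 1.51-fold (0.41 ± 0.08). S100a8 rose from 11.9 ± 7.45 to 131 ± 143 normalised reads (1.38 ± 0.28, adjusted p = 0.00989), and without 5xFADCLP replicate 11 its adjusted p was 0.0644. S100a8 passed with only CLP libraries 39 to 46 and with only 62 to 78. Its adjusted p was 0.0707 by voom, 0.343 with the number term and 0.113 with a robust spread. With the red blood cell score as a covariate it was 0.206 for S100a8, 0.121 for Podxl and 0.293 for C1qb. S100a9 rose 10.6-fold (0.88 ± 0.20, adjusted p = 0.040). Its call was lost by voom (0.121), with the number term (0.456), with a robust spread (0.208), with the red blood cell covariate (0.335), without the mice of the rarer sex (0.0754) and in libraries 39 to 46 (0.385). It was also lost without 5xFADAnesthesia replicate 1, 2, 3, 4, 6, 7 or 9 (0.0752, 0.0522, 0.0511, 0.0544, 0.0801, 0.06 and 0.0656) or 5xFADCLP replicate 6, 7, 8 or 11 (0.0895, 0.12, 0.0595 and 0.206). Each of these was above the anesthesia mean in 11 of 11 mice. In libraries 39 to 46 the log2 differences were 1.21 for Lrg1, 0.55 for Lcn2, 1.07 for Scgb3a1 and 0.69 for S100a8, and in libraries 62 to 78 they were 0.96, 0.80, 0.77 and 1.71.

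The vascular inflammation list rose in 5xFAD mice (fry adjusted p = 6.80e-07, median 0.19, 11 of 11 mice, 6 of 24 members higher, 14 adjusted over the list alone). Endothelium genes rose (adjusted p = 0.000618, median 0.08, 11 of 11 mice, 2 of 18 higher, 7 higher and 1 lower adjusted over the list alone). Reactive astrocyte genes (adjusted p = 0.00206, median 0.09, 11 of 11 mice, 1 of 15 higher, 4 adjusted over the list alone) and complement and Fc receptor genes (0.00695, median 0.09, 11 of 11 mice, 3 of 18 higher, 6 adjusted over the list alone) rose. The complement list had adjusted p = 0.209 in libraries 39 to 46. Monocyte and border macrophage genes (0.0315, median 0.08, 11 of 11 mice, 0 of 15 singly, 2 adjusted over the list alone) and lung genes (0.0202, median 0.09, 11 of 11 mice, 1 of 10 singly, 2 adjusted over the list alone) rose, each with adjusted p = 0.0585 by camera with an estimated correlation. The monocyte and border macrophage list had 0.317 in libraries 39 to 46 and 0.193 with the number term, and the lung tissue list had 3.86e-05 in libraries 39 to 46 (median 0.21) and 0.153 in libraries 62 to 78. The lung member past the threshold was Scgb3a1. Neutrophil genes had adjusted p = 0.0544 (median 0.15, 11 of 11 mice, 2 of 15 higher, 6 adjusted over the list alone), and were higher in libraries 62 to 78 (0.0228, median 0.18, against 0.144 in 39 to 46). Red blood cell genes fell (adjusted p = 0.00206, median -0.35, 10 of 11 mice, 3 of 8 lower, 4 adjusted over the list alone), with Hbb-bs at 44.7 ± 40.0 against 165 ± 99.6 normalised reads. The red blood cells list had adjusted p = 0.0583 in libraries 39 to 46 and 0.0828 with the number term. Hbb-bs, Hbb-bt and Hba-a1 are uncertain, since globin genes share reads with near-identical copies. The excitatory and synaptic lists had adjusted p = 0.297 and 0.163, but the excitatory list was lower in libraries 62 to 78 alone (adjusted p = 0.0382, median -0.04, against 0.553 in 39 to 46). Gfap had a log2 difference of 0.33 ± 0.10 that did not pass the threshold (adjusted p = 0.285). Nor did Thy1 (0.35 ± 0.10, 0.209), Il1b (0.13 ± 0.07, 0.682), Fkbp5 (0.20 ± 0.10, 0.689), Trem2 (0.12 ± 0.09, 0.817), Cst7 (-0.11 ± 0.13, 0.896), App (-0.09 ± 0.05, 0.683) or C4b (0.0028 ± 0.08, 0.996).

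After CLP 47 genes passed the threshold in 5xFAD mice, 40 higher and 7 lower. The count was 16 with only CLP libraries 39 to 46 and 189 with only 62 to 78, and 10 genes, 8 of them among the 47, were called with the red blood cell score as a covariate. It was 20 without 5xFADCLP replicate 11, and 29 and 30 without 5xFADAnesthesia replicate 6 and 7.

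**Figure D3:**
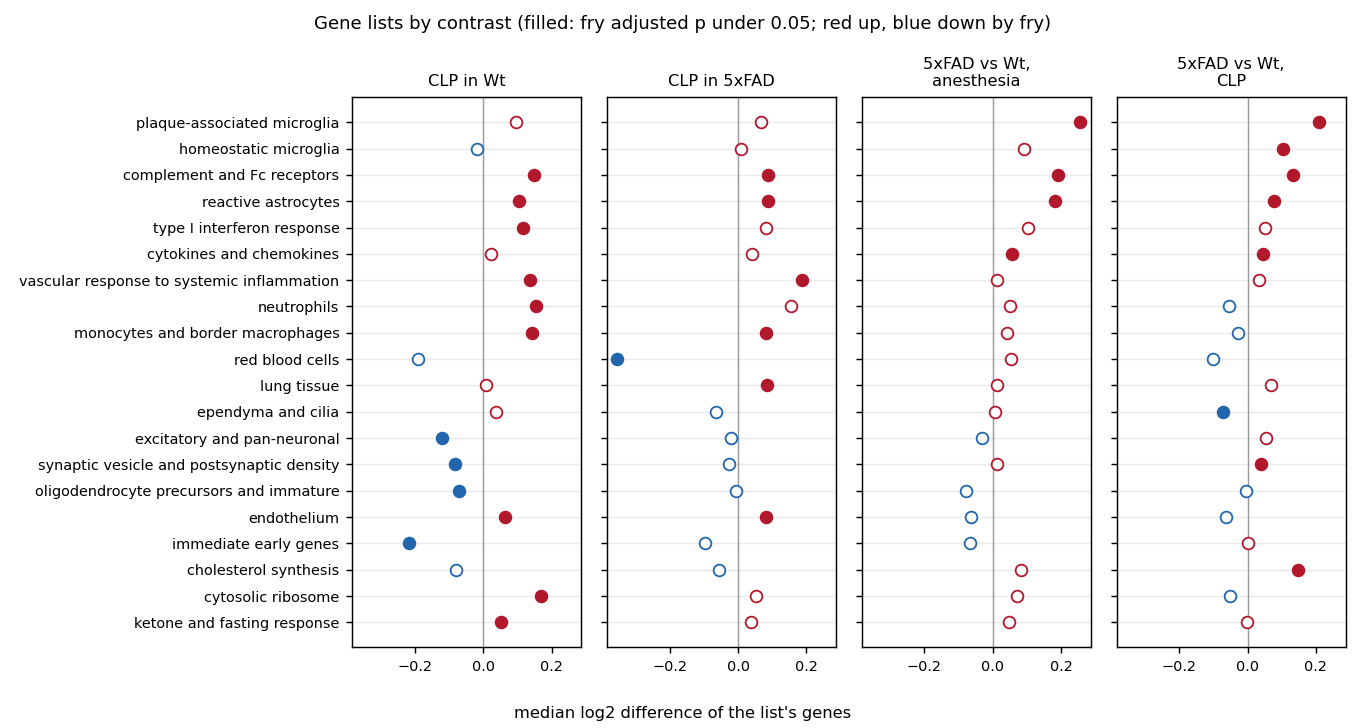
Median log2 difference of the members of each gene list called in at least 1 contrast (horizontal), for CLP in Wt, CLP in 5xFAD, and 5xFAD against Wt after anesthesia and after CLP. Filled points passed fry at an adjusted p under 0.05, red for up and blue for down. The vascular list was up after CLP in both genotypes, at 0.14 and 0.19.

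The log2 differences after CLP in Wt and in 5xFAD mice correlated at 0.244 across genes, which are not independent replicates (permutation p = 0.0200 over 100 labellings, whose others had a median of -0.01 and a maximum of 0.323). Both contrasts called 21 genes higher, where independent lists would share 0.114, and 0 lower, where 0.0221 would be shared. The covariance was 0.00168 against a permuted median of -5.68e-05. The correlation was 0.135 (permutation p = 0.0800) with only CLP libraries 39 to 46 and 0.314 with only 62 to 78. The 2 contrasts share no mice, but they share the sex term of the model. In both genotypes all anesthesia libraries, and no CLP libraries, had numbers from 47 to 61. Separate handling of the anesthesia libraries could therefore give the same agreement. Permuting treatment within genotype cannot tell it from CLP.

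After anesthesia, 5xFAD mice exceeded Wt mice in genes of plaque-associated microglia. Cst7, a cysteine protease inhibitor (chromosome 2, 150570415 to 150578944, GRCm38), was at 21.5 ± 16.2 normalised reads (SD, n = 9) against 0.693 ± 0.826 (SD, n = 6), a log2 difference of 0.93 ± 0.16 (limma adjusted p = 0.00224, higher in 9 of 9 mice). The chemokine Ccl6 was 4.73-fold higher (0.87 ± 0.14, adjusted p = 0.00157), and Tyrobp, a microglial signalling adaptor, 2.22-fold (0.79 ± 0.14, adjusted p = 0.00442). Fcer1g (0.46 ± 0.09), Ccl3 (0.56 ± 0.10), Cd84 (0.37 ± 0.08) and Clec7a (0.51 ± 0.10), immune receptors and a chemokine, were also higher, in 9, 9, 9 and 8 of 9 mice. The plaque-associated microglia list was higher (fry adjusted p = 0.000846, median 0.26, 9 of 9 mice, 5 of 28 higher, 17 adjusted over the list alone). Its score was 0.169 to 0.293 in libraries 49 to 52 and -0.145 to 0.000831 in libraries 54 to 61 of these 9 mice, against a mean of -0.172 in the Wt mice, so the difference was largest in 4 mice. With a term for anesthesia libraries of 53 and above the list had adjusted p = 0.000963. Complement and Fc receptor genes (adjusted p = 0.00167, median 0.19, 9 of 9 mice, 1 of 18 higher, 10 adjusted over the list alone) and reactive astrocyte genes (0.000846, median 0.18, 9 of 9 mice, 0 of 15 singly, 7 adjusted over the list alone) were higher. Cytokines and chemokines were higher (0.0301, median 0.06, 9 of 9 mice, 1 of 17 higher, 2 adjusted over the list alone), with adjusted p = 0.0588 by camera with an estimated correlation. For cytokines and chemokines it was 0.066 without the sex term, 0.0714 with quantile normalization, 0.148 with median centring, 0.0506 with the mouse of doubtful sex as male and 0.0587 with the term for libraries of 53 and above. Gfap (176 ± 54.1 against 116 ± 22.4 normalised reads, adjusted p = 0.542) and Trem2 (38.8 ± 16.3 against 22.4 ± 7.59, adjusted p = 0.542) did not pass the threshold, nor did App (0.11 ± 0.06, adjusted p = 0.808), whose transgene carries human coding sequence. Nor did C4b (0.27 ± 0.10, 0.697), Il1b (0.017 ± 0.08, 0.986), Fkbp5 (0.0053 ± 0.13, 0.997), Lcn2 (0.08 ± 0.15, 0.973), S100a8 (0.10 ± 0.34, 0.984) or S100a9 (0.09 ± 0.25, 0.981).

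Under anesthesia 9 genes passed the threshold, all higher in 5xFAD mice. Leaving out 5xFADAnesthesia replicate 1 gave 3 (Thy1, Cst7 and Ccl6), and the calls of Tyrobp, Fcer1g and Ccl3 were lost, with adjusted p of 0.086, 0.086 and 0.0845. The call of Clec7a was lost without WtAnesthesia replicate 1, 3, 4 or 5 (0.0803, 0.152, 0.0815 and 0.0816) or 5xFADAnesthesia replicate 1, 2, 3 or 4 (0.086, 0.0658, 0.0773 and 0.065). That of Cd84 was lost without WtAnesthesia replicate 2, 3 or 6 (0.151, 0.134 and 0.115) or 5xFADAnesthesia replicate 1, 2, 3 or 6 (0.086, 0.084, 0.0912 and 0.0561), and it was 0.0759 by voom. Between anesthesia libraries 53 to 61 and 47 to 52, with genotype and sex in the model, 61 genes differed (21 higher, 40 lower). With a term for this range 7 of the 9 genes were called, and Cd84 (0.0665) and Itgax (0.102) were not. With a robust spread the adjusted p was 0.060 for Cst7 and 0.0903 for Tyrobp. Fits of only these 2 groups, or without the 2 mice of the rarer labelled sex, called 1 gene, Thy1. Sex and genotype were nearly confounded here, with 5 of 6 Wt mice labelled female and 8 of 9 5xFAD mice labelled male. The 1 5xFAD mouse labelled female, replicate 1, had Xist at the male level (14.1 normalised reads). By transcripts only the Wt group therefore held both sexes, with 1 male.

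After CLP, 5xFAD mice showed higher microglial and reactive astrocyte transcripts than Wt mice. Cst7 stood at 19.4 ± 12.8 normalised reads (SD, n = 11) against 0.420 ± 0.927 (SD, n = 14), a log2 difference of 0.83 ± 0.11 (adjusted p = 2.20e-06, higher in 10 of 11 mice). Clec7a, a pattern-recognition receptor, was 16.3-fold higher (0.59 ± 0.07, adjusted p = 4.25e-07), the lipid-sensing receptor Trem2 2.22-fold (0.46 ± 0.07, adjusted p = 0.000182) and Gfap, the astrocyte intermediate filament, 1.94-fold (0.68 ± 0.09, adjusted p = 1.79e-06), each in 11 of 11 mice. The complement genes C1qa, C1qb and C1qc were 1.62-fold, 1.54-fold and 1.54-fold higher, and Ctsd, a lysosomal protease, 1.49-fold in 10 of 11 mice. App did not pass the threshold (0.08 ± 0.04, adjusted p = 0.770), nor did C4b (0.17 ± 0.07, adjusted p = 0.667), Il1b (0.03 ± 0.06, 0.971), Fkbp5 (0.016 ± 0.09, 0.991), Lcn2 (-0.04 ± 0.10, 0.975), S100a8 (0.09 ± 0.24, 0.976) or S100a9 (0.02 ± 0.17, 0.994).

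Among mice after CLP, the plaque-associated microglia list was higher in 5xFAD than in Wt mice (fry adjusted p = 2.47e-05, median 0.21, 11 of 11 mice, 11 of 28 members higher, 19 adjusted over the list alone). Complement and Fc receptor genes were higher (adjusted p = 0.000221, median 0.13, 11 of 11 mice, 5 of 18 higher, 10 adjusted over the list alone), as were cytokines and chemokines (0.000576, median 0.05, 10 of 11 mice, 1 of 17 higher, 7 adjusted over the list alone). Reactive astrocytes (adjusted p = 0.00224, median 0.08, 11 of 11 mice, 2 of 15 higher, 3 adjusted over the list alone) and homeostatic microglia (0.00512, median 0.10, 9 of 11 mice, 1 of 18 higher, 5 adjusted over the list alone) were higher. The astrocyte markers list did not pass and leaned lower (0.0616, median -0.05, below the Wt mean in 9 of 11 mice). Cholesterol synthesis genes were higher (0.00221, median 0.15, 9 of 11 mice, 1 of 22 higher, 11 adjusted over the list alone), among them Hsd17b7 at 1.27-fold. Ependyma and cilia genes were lower (0.00633, median -0.07, 10 of 11 mice, 0 of 14 singly), and the synaptic list was higher in 5xFAD mice (0.0311, median 0.04, 8 of 11 mice, 0 of 24 singly, 1 adjusted over the list alone) with adjusted p = 0.0572 by camera with an estimated correlation. The vascular inflammation list had adjusted p = 0.506 between the genotypes. In libraries 39 to 46 no list passed (plaque-associated microglia 0.0749, median 0.28), and in 62 to 78 there were 5 lists. Those lost in 62 to 78 were homeostatic microglia (0.0689), ependyma and cilia (0.149) and synaptic vesicle and postsynaptic density (0.316), the last also with quantile normalization (0.108) and median centring (0.0559).

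After CLP 35 genes passed the threshold between the genotypes, 34 higher and 1 lower in 5xFAD mice. The lower gene was Gm17212, annotated as a processed pseudogene and therefore uncertain. Its call was lost without 5xFADCLP replicate 1, 2, 3, 5, 6 or 9 (0.0669, 0.114, 0.0896, 0.0525, 0.0503 and 0.0587) or WtCLP replicate 2, 5, 7, 9 or 14 (0.0525, 0.063, 0.0669, 0.0674 and 0.0609). In libraries 62 to 78 the adjusted p was 0.0995 for Trem2, 0.356 for Ctsd and 0.314 for Hsd17b7. The count was 3 in libraries 39 to 46 (Thy1, Cst7 and Ccl6), 18 in 62 to 78 and 1, Thy1, in males only. The genotype differences after anesthesia and after CLP correlated at 0.0483 across genes (permutation p = 0.300, other labellings up to 0.234), with 8 shared higher genes where independent lists would share 0.0131. That correlation was 0.194 (permutation p = 0.0200) with only CLP libraries 39 to 46 and -0.03 (permutation p = 0.650) with only 62 to 78.

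**Figure D4:**
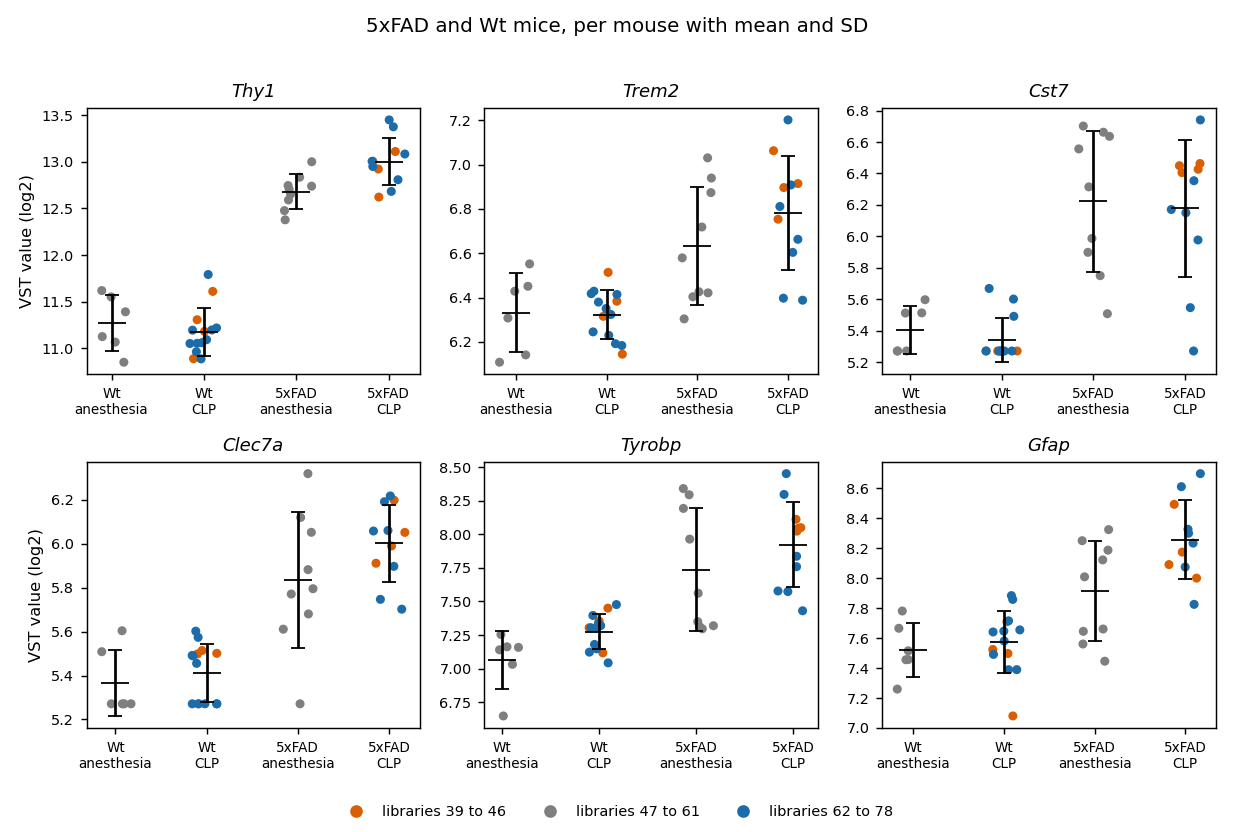
Variance-stabilised log2 values of 6 genes per mouse in the 4 groups, with group mean and SD in black and points coloured by library number. Thy1 separated the genotypes in every mouse, and Cst7 and Clec7a were near their floor in Wt mice.

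Whether 5xFAD mice responded to CLP differently from Wt mice was tested as the difference between the 2 responses. With limma 0 of 23421 genes passed the threshold (1367 at an unadjusted p under 0.05, smallest adjusted p 0.766). Voom called 1 gene, Xist (log2 difference 5.22 ± 0.85, adjusted p = 0.00268). With the mouse labelled female 5xFADAnesthesia replicate 1, which had 14.1 Xist reads, counted as male, voom called 0 genes and Xist was at -0.11 ± 0.70 (adjusted p = 0.992). The smallest p belonged to Il25 (-0.37 ± 0.09), Comp (0.37 ± 0.09), Gm44433 (-0.45 ± 0.12), Platr19 (0.41 ± 0.10) and Gm45262 (-0.39 ± 0.10), none past the threshold. The response difference was 0.46 ± 0.15 for Thy1, 0.26 ± 0.16 for Gfap, 0.10 ± 0.13 for Trem2, -0.10 ± 0.19 for Cst7 and -0.12 ± 0.18 for Lcn2. It was -0.03 ± 0.07 for App, -0.09 ± 0.13 for C4b, 0.010 ± 0.16 for Fkbp5, 0.0087 ± 0.10 for Il1b, -0.0035 ± 0.42 for S100a8 and -0.07 ± 0.31 for S100a9, all with adjusted p of 0.766 or more. No gene list passed fry (smallest adjusted p 0.488), including the excitatory list (0.488, median 0.08). Camera with the preset correlation called some lists for this difference, and their number is given below.

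Between the sexes 11 genes passed the threshold, 6 higher in mice labelled female and 5 lower. Xist was higher (log2 difference 3.82 ± 0.17), as were the X-linked Ddx3x (0.37 ± 0.05), Kdm6a (0.26 ± 0.04), Kdm5c (0.22 ± 0.04) and 5530601H04Rik (0.26 ± 0.05), and the Y-linked Ddx3y (-2.34 ± 0.13), Kdm5d (-1.40 ± 0.07), Eif2s3y (-1.32 ± 0.08) and Uty (-0.83 ± 0.07) were lower. The sixth higher gene, Socs4 on chromosome 14 (0.19 ± 0.04, adjusted p = 0.0473), was called in 6 of 16 other fits and with 15 of the 40 mice left out in turn (highest adjusted p 0.243 without WtAnesthesia replicate 3), and had 0.0978 with the mouse of doubtful sex as male. With that label 12 genes passed, 7 higher and 5 lower. Leaving out 5xFADCLP replicate 1 or 4 gave 23 or 26 genes, and total reads in the model gave 38. In the CLP mice, 0 genes had a genotype difference that differed between the sexes by limma or voom (983 at an unadjusted p under 0.05), and libraries 62 to 78 alone gave 1, Apod (-1.57 ± 0.26, adjusted p = 0.0156).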

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

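The tests of the sex label, of library number, depth and blood, and of the 9 5xFAD anesthesia mice were chosen after the results were seen, while the splits of the mice were chosen before. Of 275 values in groups of 4 to 10 mice, 27 had 1 mouse far from the others by a gap test, and chance gives about 1 in 20. That rate does not hold for the sex-linked genes of a group with 1 male. Nor does it hold for Ccl3, Comp and Selp below, where every other mouse of the group was at the floor of 5.27.

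WtAnesthesia replicate 3, the 1 male of its group, stood apart on the log2 scale in the sex-linked genes Ddx3y (8.03), Eif2s3y (6.96), Kdm5d (6.81), Uty (7.01) and Xist (5.51). It also stood apart in Hba-a1 (7.63), Hbb-bs (8.39), B2m (8.29), Homer1 (8.99) and Tesc (8.44), and in the interferon score (-0.036) and the red blood cell score (0.55). WtAnesthesia replicate 4 had Ccl3 at 5.51, Tyrobp at 6.65, an oligodendrocyte precursor score of 0.16 and a pericyte score of 0.068. Ctss was 8.48 in WtAnesthesia replicate 1, and the astrocyte score was -0.065 in WtAnesthesia replicate 5. Among 5xFAD anesthesia mice, replicate 5 had Comp at 5.61, Egr3 at 8.13 and a meningeal score of 0.22. The others were 5530601H04Rik at 6.32 in replicate 4, Ctla2a at 6.22 in replicate 2, Nrgn at 13.48 in replicate 9, Selp at 5.50 in replicate 7, an interferon score of 0.11 in replicate 1 and a hypothalamus score of -0.31 in replicate 3.

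In the library labelled female 5xFADAnesthesia replicate 1, 4 of 5 sex-linked genes lay within the range of the male-labelled libraries, which a wrong sex record, or another male 5xFAD mouse under this label, could give. An exchange with a male-labelled library of the series was argued against, since 0 of 21 such libraries had Xist at the female level. A mixture of female and male tissue was argued against too, since Xist was 1.6% of the female median, with up to 1.64% in male-labelled libraries. Which of the remaining explanations holds stays open.

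Genes higher after CLP in Wt mice might have changed only in libraries 62 to 78. For 96 genes that were higher in 5xFAD mice of that range, the score rose by 0.21 in Wt mice of libraries 39 to 46 (exact two-sided permutation p = 0.00476 over 210 splits), which argues against this. The same test for 93 lower genes gave -0.072 (p = 0.081) and stays open. With total reads in the model the median log2 difference was 0.33 against 0.35 for the higher and -0.27 against -0.28 for the lower genes, of which 40 of 67 and 35 of 74 were called, so depth alone was argued against. None of the anesthesia libraries (0 of 15) fell in the CLP number ranges, so the effect of CLP and separate handling of the anesthesia libraries cannot be told apart for the higher or the lower genes.

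More residual blood could have raised S100a8 and S100a9 after CLP. In 5xFAD mice the red blood cells list fell (median log2 difference -0.35, fry adjusted p = 0.00206). This argues against it there only as far as red blood cell transcripts follow the blood content, which was not tested. The list did not pass fry in libraries 39 to 46 (adjusted p = 0.0583) or with the number term (0.0828), and its globin genes are uncertain. In Wt mice the median was -0.19 with fry adjusted p = 0.161, which decides nothing, and WtCLP replicate 11 had both the highest neutrophil score (0.86) and the highest red blood cell score (0.52) of its group, so it stays open there. Residual blood with more neutrophils stays open, as the neutrophil list had fry adjusted p of 0.00816 in Wt and 0.0544 in 5xFAD mice, and 0.0228 in 5xFAD mice of libraries 62 to 78. Neutrophils within the tissue were not told apart from those in vessels.

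Other splits of the same mice were counted among 100, the real one included. For CLP in Wt mice 2 splits, the real one included, gave as many as 141 genes. The other gave 279 genes with 4 of the 6 true anesthesia mice in its smaller group, so this count does not exclude chance. It points to a structure of the samples whose cause was not tested. In that group WtAnesthesia replicates 2 to 5 and WtCLP replicate 13 had cytosolic ribosome scores of -0.299 to -0.088, and WtCLP replicate 3 had 0.033. The remaining Wt mice had 0.00046 to 0.158. These scores were looked up after the split was seen. For CLP in 5xFAD mice 1 split, the real one, gave 47 genes, with at most 3 in another. For genotype after anesthesia 3 splits, the real one included, gave 9 or more, and the others gave 64 and 31. Larger counts thus came from wrong groupings, so the count of 9 does not exclude chance. Both other splits grouped 5xFADAnesthesia replicates 5 and 8 with WtAnesthesia replicates 3, 4 and 5, which again points to a structure. These 5 mice had library numbers 53 to 60 and scores of -0.98 to 7.79 on the first principal component, against -10.8 to -2.45 in libraries 47 to 52, while libraries 57 to 59 had -5.90 to -4.70. The structure therefore went with library number only in part, and with a term for libraries of 53 and above 7 of the 9 genes were called. For genotype after CLP 1 split, the real one, gave 35 genes (highest other 3), which argues against chance. For sex 1 split, the real one, gave 11 (highest other 8). Most of those 11 genes were X- or Y-linked and follow sex itself, so this count says little about other sex differences. For the difference between the responses and for sex by genotype the real count was 0, which all 100 splits reach whatever the data, so these counts say nothing about chance (highest other 5 and 4). The list counts of 13, 7, 4 and 8 for CLP in Wt, CLP in 5xFAD, genotype after anesthesia and genotype after CLP were reached by 1, 1, 2 and 1 splits (highest other 4, 1, 4 and 3), while those of 0 for the response difference and sex are reached by all 100 whatever the data (highest other 4 and 1).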

How the results depend on the processing

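Chosen after the data were seen were voom (with either sex label), total reads, the changed or omitted mouse of doubtful sex, and the fits by library number. Counts are genes past the threshold, and the cause was not tested for any change given here. Mice of the rarer sex under anesthesia are so named by their labels. They are WtAnesthesia replicate 3 and the mouse of doubtful sex, 5xFADAnesthesia replicate 1, which had Xist at the male level.

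For CLP in Wt mice the count of 141 became 65 in females, 46 without the 2 mice of the rarer sex under anesthesia, 78 with quantile normalization, 228 and 81 with the choroid plexus and red blood cell scores, 22 and 732 in libraries 39 to 46 and 62 to 78, 31 with a number term and 78 with total reads. It ran from 49 (without WtAnesthesia replicate 3) to 253 (without WtCLP replicate 1). For CLP in 5xFAD mice 47 became 72 with library weights, 78 and 10 with the choroid plexus and red blood cell scores, 16 and 189 in the ranges and 25 with a number term, and ran from 20 (without 5xFADCLP replicate 11) to 66. For genotype after anesthesia 9 became 1 with the 2 groups alone, 1 without the mice of the rarer sex and 3 without 5xFADAnesthesia replicate 1, and ran from 3 to 11. For genotype after CLP 35 became 1 in males and 3 and 18 in the ranges, and ran from 25 to 46. The response difference went from 0 to 1 by voom, was 0 by voom with the changed sex label, and stayed at 0 with each mouse left out. For sex 11 became 7 and 29 in the ranges and 38 with total reads, and ran from 10 to 26 (without 5xFADCLP replicate 4). Sex by genotype went from 0 to 1 in libraries 62 to 78.

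With camera and a preset correlation, 14 lists were called for CLP in 5xFAD, 11 and 16 for genotype after anesthesia and after CLP, 4 for the response difference and 3 for sex. Genotype after CLP had 0 and 5 lists in the ranges. The correlation of CLP responses was 0.135 in 39 to 46, and that of genotype effects was 0.194 in 39 to 46 and -0.034 in 62 to 78. Single genes changed sign as follows on the log2 scale, with the reported value in parentheses, and apart from Hba-a1 and Hbb-bt none had passed the threshold.

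For CLP in Wt mice, Cst7 (-0.016) was 0.027 without the mice of the rarer sex, 0.010 with library weights, 0.062 in 62 to 78, 0.065 with a number term and 0.0017 with total reads, and ran from -0.047 to 0.047 with each mouse left out. Gfap (0.068) was -0.0066 with the 2 groups alone, -0.071 in 39 to 46 and -0.034 with a number term. Trem2 (0.016) was -0.0085 without a sex term, -0.0083 with the 2 groups alone, -0.0062 with quantile normalization and -0.0039 with median centring, and ran from -0.030 to 0.064 with each mouse left out.

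For CLP in 5xFAD mice, C4b (0.0028) was -0.025 with library weights, -0.0033 with quantile normalization, -0.0062 with the choroid plexus score, -0.021 with the red blood cell score, -0.060 in 62 to 78 and -0.0014 by voom, and ran from -0.038 to 0.047 with each mouse left out. Cst7 (-0.11) was 0.18 in 39 to 46, and ran from -0.20 to 0.0017 with each mouse left out. Hba-a1 (-0.86) was 0.0039 with the red blood cell score, and ran from -0.95 to -0.77 with each mouse left out. Hbb-bt (-0.63) was 0.0042 with the red blood cell score, and ran from -0.74 to -0.57 with each mouse left out. Hba-a1 and Hbb-bt are themselves members of the list behind that score. The covariate therefore takes out most of their difference in advance, and these sign changes say nothing about how stable it is.

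For genotype after anesthesia, Fkbp5 (0.0053) was -0.011 without a sex term, -0.028 without the mice of the rarer sex, -0.0085 with library weights, -0.0026 with quantile normalization, -0.0069 with median centring, -0.0050 with the red blood cell score, -0.010 without the mouse of doubtful sex and -0.00079 with a term for libraries of 53 and above, and ran from -0.030 to 0.058 with each mouse left out. Il1b (0.017) was -0.11 with the 2 groups alone and -0.021 with the red blood cell score, and ran from -0.016 to 0.064 with each mouse left out. S100a8 (0.095) was -0.075 without the mice of the rarer sex, and ran from -0.051 to 0.15 with each mouse left out. S100a9 (0.086) was -0.024 without the mice of the rarer sex, and ran from -0.028 to 0.14 with each mouse left out.

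For genotype after CLP, Fkbp5 (0.016) was -0.19 in females and -0.026 in 62 to 78, and ran from -0.046 to 0.083 with each mouse left out. Il1b (0.025) was -0.086 in females and -0.10 in 39 to 46. Lcn2 (-0.041) was 0.12 in males and 0.069 in 62 to 78, and ran from -0.17 to 0.0041 with each mouse left out. S100a8 (0.092) was -0.28 in females, and ran from -0.089 to 0.31 with each mouse left out. S100a9 (0.020) was -0.22 in females and -0.014 in 39 to 46, and ran from -0.10 to 0.17 with each mouse left out.

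For the difference between the responses, App (-0.028) was 0.057 without a sex term, and ran from -0.052 to 0.0037 with each mouse left out. Cst7 (-0.096) was 0.021 without a sex term and 0.31 in 39 to 46, and ran from -0.17 to 0.040 with each mouse left out. Fkbp5 (0.010) was -0.064 in 62 to 78, and ran from -0.084 to 0.12 with each mouse left out. Il1b (0.0087) was -0.040 without a sex term, -0.085 without the mice of the rarer sex, -0.0088 with the changed sex label, -0.040 without the mouse of doubtful sex and -0.077 in 39 to 46, and ran from -0.040 to 0.054 with each mouse left out. Lcn2 (-0.12) was 0.065 in 62 to 78. S100a8 (-0.0035) was 0.17 without the mice of the rarer sex, 0.14 with library weights, 0.0082 with quantile normalization, 0.014 with median centring, 0.023 with the changed sex label, 0.0034 without the mouse of doubtful sex, 0.13 in 62 to 78 and 0.0035 with total reads, and ran from -0.28 to 0.36 with each mouse left out. S100a9 (-0.066) was 0.046 without the mice of the rarer sex, 0.040 with library weights and 0.080 in 62 to 78, and ran from -0.25 to 0.18 with each mouse left out.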

Other observations

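The tests of the 9 5xFAD anesthesia mice were chosen after the result was seen, and the 4 tests of the vascular score before.

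Whether CLP mice with a higher vascular inflammation score also had a higher plaque-associated microglia score or a lower excitatory neuron score was tested over 14 Wt and 11 5xFAD mice, 4 relations in all. Spearman's rho with the plaque score was 0.125 in Wt mice (permutation p = 0.669, adjusted 0.798, Pearson's r = 0.422, p = 0.133, adjusted 0.533) and -0.473 in 5xFAD mice (p = 0.148, adjusted 0.591, r = -0.332, p = 0.312, adjusted 0.624). With the excitatory score rho was 0.0769 (p = 0.798, adjusted 0.798, r = 0.16, p = 0.584, adjusted 0.663) and 0.227 (p = 0.502, adjusted 0.798, r = 0.142, p = 0.663, adjusted 0.663). Without the 2 farthest mice r was 0.395 and 0.0436 with the plaque score and 0.137 and 0.76 with the excitatory score. In libraries 62 to 78 rho was -0.2 and -0.536 with the plaque score and 0.176 and 0.357 with the excitatory score. The r of 0.76 ran against the tested direction (permutation p = 0.0159, adjusted over the 4 relations 0.0635). None of the 4 relations passed the threshold, so all 4 stay open.

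The 9 5xFAD anesthesia mice ranged from -0.145 to 0.293 in the plaque-associated microglia score, which may follow library number. Libraries 49 to 52 had 0.169 to 0.293 and libraries 54 to 61 had -0.145 to 0.000831, so the relation rests largely on a split into 2 sets of 4 and 5 mice. Within the 5 mice of libraries 54 to 61 rho was -0.2 (exact permutation p = 0.783) and r was -0.275 (exact permutation p = 0.675), a test chosen after the split was seen. Spearman's rho with the number was -0.867 (exact permutation p = 0.00451, adjusted over 2 relations 0.00902) and Pearson's r was -0.91 (exact permutation p = 0.00387, adjusted 0.00774), or -0.957 without the 2 farthest mice. With total reads rho was -0.133 (exact permutation p = 0.744, adjusted 0.744) and r was -0.0895 (p = 0.808). The labels do not say what the number stands for, so an order of age, litter or handling stays open and untested.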
